A study of Mus musculus with 12 samples.

How the data were processed

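Poly(A) RNA of 12 mouse liver samples was sequenced as stranded libraries on a BGI platform per the labels, 3 samples in each of 4 groups (normal or high-fat diet, sham or ischemia-reperfusion). The deposited table gave TPM per gene symbol and sample, computed by the authors against mouse build GRCm39 per the processing notes. Aligner, counting tool, gene annotation and use of strand were not given in the sources used here, and no coordinates were used. Each sample's values had the same total, as TPM do, so depth and counting precision could not be derived. A second sheet of the workbook held 23 sample columns for 6 genes that could not be matched to the samples and was not used.

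The table held 25947 entries after 2 blank ones were dropped, with 18 repeated symbols kept apart, and 807 were at 0 in all samples. Genes with at least 1 TPM in at least 3 of the 12 samples were tested (13364). Values were transformed as log2(TPM + 1), and a linear model with a mean per group was fitted in limma 3.58.1 (R 4.3.3) with a variance trend. The 5 contrasts were IRI against sham on each diet, the diets in sham and in IRI livers, and the difference between the IRI effects. Tests were two-sided, with p-values adjusted for 5% false discoveries per contrast. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

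Gene lists written by hand (38) were tested where at least 5 members passed the filter, which left 37; the list of exocrine pancreas, gut and adipose markers had 3 members and was not tested. Lists were compared with all other tested genes by camera with a preset correlation of 0.01, and beside it with a correlation estimated per list. Each list was also tested by fry, which asks whether its members changed together in the same direction, without reference to other genes. Its direction can therefore differ from that of camera, and a list whose members moved in opposite directions can go uncalled. Each p was adjusted over the lists of a contrast. Groups, contrasts, filter, lists, naming rule and alternatives were set before the data were examined.

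Named genes followed a rule. Per contrast it took the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 TPM in the higher group and no overlap between the groups, leaving out predicted and unnamed genes. For the difference between the IRI effects, the 5 TPM applied to the highest of the 4 groups, and overlap was not considered. The rule added 2 members moving in the list's direction for each of the 8 called lists with the smallest p, and Hmox1, Cidec and Alb throughout. Members moving against their list were added as examples. Adipoq, Lcn2, Tmem171, Lce1d, Pdk4, Igfbp1, Saa1, Jchain, Atf3 and Per1 fall outside the rule and were chosen after their values were seen. Some results that the rule would name are not reported here.

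The alternatives were a pseudocount of 0.1, no filter, a filter at 5 TPM, median-ratio scaling, quantile normalization, TPM re-closed without mitochondrial genes and the 50 most abundant genes, no variance trend, sample weights, the replicate number as a block, only the groups compared, a log2 fold change of at least 1, and leaving out each library. Leaving out the first ND-Sham and ND-IRI libraries together was added after seeing the data. The iteration for the sample weights ended before converging. The method was tested on simulated data with the sizes of these groups, the ND-Sham means and the spread of each gene. Noise was drawn independently for each gene, so correlation between genes and further structure among the samples were not simulated. Changes were given only to more abundant genes, so recovery of genes near the filter was not measured. Of 100 genes with a simulated log2 change of 1, 69, 81, 75, 78 and 43 were recovered in the 5 contrasts in the order above, and of 100 with a change of 2, 98, 96, 97, 96 and 89, with 9, 8, 6, 14 and 7 false calls.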

Results

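Liver RNA was sequenced from 12 samples of mice in 4 groups of 3, formed by crossing diet with operation. Mice ate a normal diet (ND) or a high-fat diet (HFD) for 4 months, the latter as a model of hepatic steatosis, and then had a sham operation or hepatic ischemia-reperfusion injury (IRI). In IRI, part of the liver's blood inflow was tied off for 1 h and reopened, and tissue was taken after 6 h of reperfusion. The deposited values were TPM, a length-normalized scale with the same total for every library, so that the sequencing depth of each library was unknown and no counting interval could be given. Between 18935 and 20425 genes per library had a TPM above 0, the 50 most abundant genes took 44.4% to 49.3% of each library's total, and mitochondrially encoded genes took 9.43% to 15.2%. The labels name separate samples without stating more, so the p-values measure the spread between these samples, which may be technical.

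Differences were tested for 13364 genes on log2(TPM + 1) with limma, two-sided, and a gene was called at an adjusted p under 0.05. Log2 fold changes are on that scale, which understates changes of genes near 0 TPM. Group values are mean ± SD TPM (n = 3 libraries). With 3 libraries against 3, an exact permutation test of a single gene could not give a p below 0.1. Genes are named by symbol, the only identifier used here. Members of close families (Mup, Cyp4a, Cyp2a, Cyp2b, Cyp2c, Serpina1, Hspa1, the globins) can share reads, so a change of a single member is uncertain.

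Operation and diet separated the libraries along the first components. The first principal component, 60.0% of the variance, placed the 6 IRI libraries opposite the 6 sham libraries, and the second, 13.6%, placed the 6 ND libraries opposite the 6 HFD libraries. Pairs of libraries of a group correlated at r = 0.970 to 0.991 across genes, against 0.873 to 0.977 for pairs from different groups. Genes are not independent replicates in these correlations. Component 3, 8.13%, did not follow the groups. On it ND-Sham 1 (score 30.5) stood apart from ND-Sham 2 (-17.0) and ND-Sham 3 (-10.2), and ND-IRI 1 (-20.1) stood apart from ND-IRI 2 (25.4) and ND-IRI 3 (23.7). The first ND-Sham library held 11.6 TPM of the adipocyte transcript Adipoq, against at most 0.23 in every other library, which was looked up after the values were seen. Each count of called genes is therefore also given without these first ND-Sham and ND-IRI libraries, an alternative chosen after seeing the data.

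**Figure D1:**
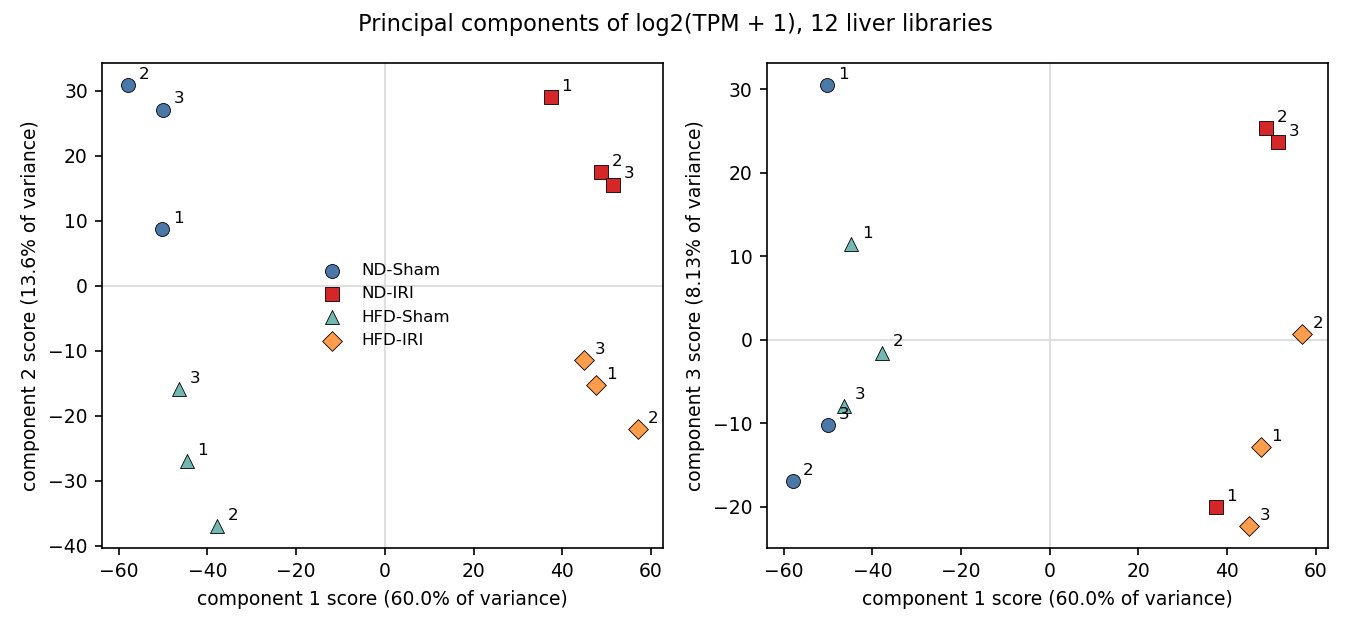
Principal component scores of the 12 liver libraries on log2(TPM + 1) of the tested genes, component 1 (60.0% of variance) on the horizontal axis and component 2 (13.6%, left) or 3 (8.13%, right) on the vertical axis. Each point is a library, numbered by replicate; colour and symbol give the group, and the right panel shows ND-Sham 1 (30.5) apart from the other ND-Sham libraries.

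The comparison of IRI with sham livers on the normal diet asked what ischemia-reperfusion changed in livers without steatosis. Of the tested members, 24 of 24 in the chemokine and cytokine list (which includes adhesion molecules), 16 of 18 heat shock genes and 17 of 26 acute phase genes rose. In other lists, 22 of 26 fatty acid oxidation, 10 of 18 bile acid and 16 of 22 xenobiotic genes fell. These list calls were lost with an estimated correlation (adjusted p = 0.235 to 0.347). Among the largest rises, Ccl2 and Ccl7, chemokines that recruit monocytes, rose from 1.13 ± 0.488 to 81.3 ± 9.34 TPM and from 0.367 ± 0.304 to 45.2 ± 3.12 TPM (log2 fold change 5.29, SE 0.509, adjusted p = 1.35e-05, and log2 fold change 5.10, SE 0.476, adjusted p = 1.13e-05). The stress-inducible chaperone transcripts Hspa1b, Hspa1a and Hspb1 rose by 6.39, 5.58 and 5.19 on the log2 scale. Sprr1a, a small proline-rich protein of stressed epithelia, rose from 0.0433 ± 0.0751 to 149 ± 83.0 TPM. Among the largest falls were those of Cyp4a14 and Cyp4a10, microsomal fatty acid omega-hydroxylases, from 3684 ± 1544 to 167 ± 61.9 TPM (log2 fold change -4.44, SE 0.353, adjusted p = 3.91e-06) and from 2218 ± 382 to 132 ± 32.9 TPM (log2 fold change -4.08, SE 0.208, adjusted p = 4e-07).

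Further large falls were those of Cyp7a1, the rate-limiting enzyme of bile acid synthesis, from 90.3 ± 14.3 to 4.33 ± 1.44 TPM (log2 fold change -4.12, adjusted p = 2.18e-05), and of Upp2, a uridine phosphorylase, from 211 ± 52.7 to 17.8 ± 9.75 TPM (-3.58, adjusted p = 4.24e-05). Dbp and Ciart, output and repressor genes of the circadian clock, fell from 73.3 ± 34.5 to 4.94 ± 4.77 TPM (-3.83, adjusted p = 0.000233) and from 64.9 ± 13.0 to 5.22 ± 1.84 TPM (-3.43, adjusted p = 2.31e-05). Hmox1, heme oxygenase 1, rose from 41.8 ± 23.1 to 1036 ± 129 TPM (log2 fold change 4.77, SE 0.424, adjusted p = 8.05e-06). Cidec, a lipid droplet protein, was at 31.3 ± 7.43 and 54.9 ± 16.6 TPM (adjusted p = 0.256), and albumin, Alb, at 77587 ± 9732 and 74653 ± 11704 TPM (adjusted p = 0.8). The sign of the Alb estimate, -0.06, turned to 0.05 without ND-IRI 3.

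On the normal diet, of the neutrophil chemokines and inflammatory cytokines, 24 of 24 tested members rose (adjusted over the list alone, 24 rose and 0 fell), with camera adjusted p = 2.39e-11, and adjusted p = 0.235 with an estimated correlation. Il1rn, the interleukin 1 receptor antagonist, rose from 2.15 ± 0.439 to 56.3 ± 13.6 TPM (4.16, adjusted p = 6.64e-07). Lif, a cytokine of the interleukin 6 family, rose from 0.0667 ± 0.0569 to 5.69 ± 0.767 TPM (2.64, adjusted p = 1.74e-06). Of the neutrophil markers, 14 of 16 tested members rose, 1 fell and 1 did not pass (adjusted over the list alone, 14 rose and 1 fell), with camera adjusted p = 1.8e-05, and adjusted p = 0.347 with an estimated correlation. S100a9, a granulocyte calcium-binding protein, rose from 9.86 ± 1.21 to 271 ± 129 TPM. Mmp8, neutrophil collagenase, rose from 0.113 ± 0.0666 to 17.0 ± 7.42 TPM. The marker that fell, G0s2, also an inhibitor of triglyceride lipase, fell from 491 ± 236 to 159 ± 3.20 TPM (-1.52, adjusted p = 0.00142). Of the acute phase proteins, 17 of 26 tested members rose and 9 did not pass (adjusted over the list alone, 18 rose and 0 fell), with camera adjusted p = 5.68e-05, and adjusted p = 0.347 with an estimated correlation. Serpina3n, a protease inhibitor, rose from 660.1 ± 60.5 to 5602 ± 1351 TPM. Steap4, a metalloreductase, rose from 65.3 ± 6.66 to 1749 ± 785 TPM. Lcn2, an acute phase and neutrophil transcript chosen after its values were seen, was at 134 TPM in ND-IRI 1 against 843 and 639 in the other ND-IRI libraries.

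Of the heat shock proteins and chaperones, 16 of 18 tested members rose and 2 did not pass (adjusted over the list alone, 16 rose and 0 fell), with camera adjusted p = 7.97e-07, and adjusted p = 0.347 with an estimated correlation. Hsp90aa1, the inducible cytosolic chaperone, rose from 73.5 ± 7.11 to 1313 ± 423 TPM (log2 fold change 4.10, SE 0.235, adjusted p = 6.5e-07). Hspb1 rose from 26.6 ± 11.3 to 961 ± 224 TPM. Of the immediate early genes, 21 of 24 tested members rose and 3 did not pass (adjusted over the list alone, 21 rose and 0 fell), with camera adjusted p = 2e-05, and adjusted p = 0.347 with an estimated correlation. Ier3 and Ier5, early response genes, rose from 4.41 ± 0.840 to 118 ± 1.81 TPM and from 4.97 ± 1.13 to 57.4 ± 6.14 TPM. In this list ND-Sham 1 was at 2.25 TPM of Atf3, a stress-response transcription factor chosen after its values were seen, against 72.8 and 67.2 in the other ND-Sham libraries. ND-IRI 1 was at 621 TPM of Atf3 against 297 and 341. Without both libraries the camera adjusted p of the list was 0.0162. For the unfolded protein and integrated stress response, 19 of 24 tested members rose, 2 fell and 3 did not pass (adjusted over the list alone, 20 rose and 3 fell), with camera adjusted p = 6.44e-05, and adjusted p = 0.347 with an estimated correlation. Among hypoxia targets, 14 of 19 tested members rose, 2 fell and 3 did not pass (adjusted over the list alone, 14 rose and 2 fell), with camera adjusted p = 0.00197, and adjusted p = 0.347 with an estimated correlation, and adjusted p = 0.0758 without the first ND-Sham and ND-IRI libraries. Of the glycolysis genes, 10 of 16 tested members rose, 1 fell and 5 did not pass (adjusted over the list alone, 10 rose and 1 fell), with camera adjusted p = 0.00273, and adjusted p = 0.347 with an estimated correlation.

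For fatty acid oxidation and ketogenesis, 1 of 26 tested members rose, 22 fell and 3 did not pass (adjusted over the list alone, 2 rose and 22 fell), with camera adjusted p = 2.39e-11, and adjusted p = 0.235 with an estimated correlation. Acot2, a mitochondrial acyl-CoA thioesterase, rose from 26.2 ± 11.3 to 99.4 ± 17.0 TPM (1.98, adjusted p = 0.000859). Of the pericentral hepatocyte genes, 14 of 17 tested members fell and 3 did not pass (adjusted over the list alone, 0 rose and 14 fell), with camera adjusted p = 1.2e-07, and adjusted p = 0.235 with an estimated correlation. Cyp2e1, an ethanol- and fatty acid-metabolizing cytochrome P450, fell from 11633 ± 688 to 2471 ± 282 TPM (log2 fold change -2.24, SE 0.155, adjusted p = 1.83e-06). Oat, ornithine aminotransferase, fell from 2126 ± 574 to 453 ± 101 TPM. Of the xenobiotic cytochromes P450 and transferases, 1 of 22 tested members rose, 16 fell and 5 did not pass (adjusted over the list alone, 1 rose and 16 fell), with camera adjusted p = 1.2e-07, and adjusted p = 0.251 with an estimated correlation. Nr1i3, the constitutive androstane receptor, fell from 71.2 ± 12.4 to 6.08 ± 2.16 TPM (-3.38, adjusted p = 5.21e-06). Of the bile acid synthesis and transport genes, 1 of 18 tested members rose, 10 fell and 7 did not pass (adjusted over the list alone, 1 rose and 10 fell), with camera adjusted p = 0.000107, and adjusted p = 0.235 with an estimated correlation. Of the circadian clock genes, 5 of 17 tested members rose, 8 fell and 4 did not pass (adjusted over the list alone, 5 rose and 8 fell), with camera adjusted p = 0.0488, and adjusted p = 0.452 with an estimated correlation. The clock call was lost under every scaling alternative, with adjusted p up to 0.224, and without ND-Sham 2, ND-Sham 3, ND-IRI 2 or ND-IRI 3, with adjusted p up to 0.119.

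Markers of blood cells rose as well. Of the red blood cell and platelet markers, 9 of 9 tested members rose (adjusted over the list alone, 9 rose and 0 fell), with camera adjusted p = 0.00485, and adjusted p = 0.347 with an estimated correlation. The haemoglobin transcripts Hbb-bs and Hba-a1 rose from 21.1 ± 3.87 to 441 ± 349 TPM (4.07, adjusted p = 0.000131) and from 17.0 ± 1.62 to 256 ± 199 TPM (3.58, adjusted p = 0.000291), in the same livers as the neutrophil and acute phase groups.

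In all, 6248 of 13364 genes were called on the normal diet, 4035 higher and 2213 lower in IRI livers. With a log2 fold change of at least 1 the count was 2523 (1827 higher, 696 lower). The median log2 fold change of all tested genes was 0.16, which median-ratio scaling shifted by -0.17 and quantile normalization by -0.22, and the calls then divided into 3437 higher and 3384 lower, or 3180 higher and 3860 lower. Without the first ND-Sham and ND-IRI libraries, 5342 genes were higher and 1794 lower. Of 37 lists tested, 25 were called by camera (12 up and 13 down relative to the other genes, a balance that turned under several alternatives, such as 14 and 6 with quantile normalization and 11 and 9 without ND-Sham 2) and 0 with an estimated correlation (smallest adjusted p = 0.235), while fry called 25 (17 up, 8 down). These were not the same lists: fry called 20 of those called by camera. The other 5 were Kupffer cell, periportal, cholesterol synthesis, mitochondrially encoded and clock genes (fry adjusted p = 0.0692 to 0.416).

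The comparison of IRI with sham livers on the high-fat diet asked the same question in steatotic livers. Of the tested members, 22 of 24 in the chemokine and cytokine list, 15 of 16 neutrophil markers and 13 of 18 heat shock genes rose. In other lists, 19 of 26 fatty acid oxidation, 12 of 18 bile acid and 12 of 17 pericentral genes fell. These list calls were lost with an estimated correlation (adjusted p = 0.483 for each). The largest rise was that of Sult1e1, estrogen sulfotransferase, from 1.13 ± 0.117 to 166 ± 58.3 TPM (log2 fold change 6.24, SE 0.789, adjusted p = 8.91e-05). Hspa1b and Hspa1a rose by 5.77 and 5.40 on the log2 scale. Socs3, a feedback inhibitor of cytokine signalling, rose from 10.04 ± 2.68 to 362 ± 48.1 TPM (5.06, adjusted p = 1.13e-06). Adamts4, an extracellular matrix protease, rose from 0.813 ± 0.263 to 55.2 ± 12.1 TPM (4.94, adjusted p = 7.65e-07). Acot4, a peroxisomal acyl-CoA thioesterase, fell from 144 ± 16.8 to 16.2 ± 5.54 TPM (log2 fold change -3.12, SE 0.184, adjusted p = 9.63e-07). Inhbe, which encodes a liver-secreted activin subunit, fell from 76.7 ± 21.2 to 5.00 ± 0.859 TPM (-3.66, adjusted p = 2.8e-05).

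Other large falls on the high-fat diet were those of Dlec1, from 24.1 ± 10.6 to 0.930 ± 0.140 TPM (-3.59, adjusted p = 0.0018), of Tlr12, a Toll-like receptor, from 24.1 ± 10.2 to 1.83 ± 0.455 TPM (-3.08, adjusted p = 2.53e-05), and of Glt1d1, a glycosyltransferase domain gene, from 59.1 ± 11.6 to 6.41 ± 1.46 TPM (-3.02, adjusted p = 4.25e-06). Igkj3, an immunoglobulin kappa joining segment, was at 12.5 ± 4.75 TPM in HFD-Sham livers and was listed at 0 in the 3 HFD-IRI libraries (adjusted p = 0.0168, and 0.0537 without HFD-Sham 1). Hmox1 rose from 86.2 ± 47.9 to 1209 ± 275 TPM (log2 fold change 3.90, SE 0.424, adjusted p = 2.96e-05). Cidec was at 184 ± 143 and 163 ± 81.2 TPM (log2 fold change -0.03, adjusted p = 0.97), an estimate that turned to 0.57 without HFD-Sham 2 and to 0.50 without HFD-IRI 3. Alb was at 71818 ± 8619 and 68019.5 ± 4601 TPM (adjusted p = 0.752).

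Of the neutrophil chemokines and inflammatory cytokines, 22 of 24 tested members rose and 2 did not pass (adjusted over the list alone, 22 rose and 0 fell) on the high-fat diet, with camera adjusted p = 4.23e-08, and adjusted p = 0.483 with an estimated correlation. Selp, the endothelial and platelet adhesion molecule P-selectin, rose from 1.03 ± 0.116 to 22.96 ± 8.99 TPM (3.496, adjusted p = 2.56e-06). Il1rn rose from 8.38 ± 1.96 to 52.4 ± 15.2 TPM. Of the neutrophil markers, 15 of 16 tested members rose and 1 fell (adjusted over the list alone, 15 rose and 1 fell), with camera adjusted p = 8.28e-06, and adjusted p = 0.483 with an estimated correlation. Retnlg, a resistin-like granulocyte protein, rose from 0.523 ± 0.356 to 31.1 ± 18.3 TPM. Il1r2, a decoy interleukin 1 receptor, rose from 0.180 ± 0.0755 to 17.5 ± 6.85 TPM. G0s2 fell from 951 ± 149 to 193 ± 62.7 TPM. Of the heat shock proteins and chaperones, 13 of 18 tested members rose and 5 did not pass (adjusted over the list alone, 15 rose and 0 fell), with camera adjusted p = 9.57e-06, and adjusted p = 0.483 with an estimated correlation. Hsp90aa1 and Hspb1 rose from 115 ± 16.6 to 1220.2 ± 363 TPM and from 51.7 ± 15.3 to 673 ± 187 TPM. Of the immediate early genes, 12 of 24 tested members rose and 12 did not pass (adjusted over the list alone, 13 rose and 0 fell), with camera adjusted p = 0.000263, and adjusted p = 0.483 with an estimated correlation. Ier3 and Ier5 rose by 4.03 and 2.95 on the log2 scale. Of the acute phase proteins, 14 of 26 tested members rose and 12 did not pass (adjusted over the list alone, 14 rose and 1 fell), with camera adjusted p = 0.000375, and adjusted p = 0.483 with an estimated correlation.

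For fatty acid oxidation and ketogenesis on the high-fat diet, 1 of 26 tested members rose, 19 fell and 6 did not pass (adjusted over the list alone, 1 rose and 20 fell), with camera adjusted p = 1.72e-06, and adjusted p = 0.483 with an estimated correlation. Cpt1a, which controls entry of fatty acids into mitochondria, fell from 303 ± 49.4 to 88.4 ± 7.78 TPM (log2 fold change -1.76, SE 0.140, adjusted p = 4.87e-06). Bdh1, a ketone body enzyme, fell from 280.0 ± 23.8 to 116 ± 8.46 TPM (-1.27, adjusted p = 2.01e-05). Of the pericentral hepatocyte genes, 12 of 17 tested members fell and 5 did not pass (adjusted over the list alone, 0 rose and 12 fell), with camera adjusted p = 0.000271, and adjusted p = 0.483 with an estimated correlation. Glul, glutamine synthetase, fell from 916 ± 107 to 447 ± 37.9 TPM (-1.03, adjusted p = 0.000932). Lgr5, a Wnt pathway receptor, fell from 1.99 ± 0.632 to 0.30 ± 0.0656 TPM (-1.18, adjusted p = 0.00044). Of the bile acid synthesis and transport genes, 1 of 18 tested members rose, 12 fell and 5 did not pass (adjusted over the list alone, 1 rose and 12 fell), with camera adjusted p = 0.000399, and adjusted p = 0.483 with an estimated correlation. Of the fatty acid synthesis genes, 1 of 20 tested members rose, 8 fell and 11 did not pass (adjusted over the list alone, 1 rose and 8 fell), with camera adjusted p = 0.0157, and adjusted p = 0.601 with an estimated correlation. The camera call was lost without HFD-Sham 2 (adjusted p = 0.0644) and with quantile normalization (0.0746). Of the cytosolic ribosomal proteins, 14 of 22 tested members rose and 8 did not pass (adjusted over the list alone, 16 rose and 0 fell), with camera adjusted p = 0.000308, and adjusted p = 0.601 with an estimated correlation. Rpl10a and Rplp0 rose from 131 ± 15.9 to 193 ± 2.95 TPM and from 484 ± 28.9 to 683 ± 17.4 TPM.

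Of the red blood cell and platelet markers, 7 of 9 tested members rose and 2 did not pass (adjusted over the list alone, 8 rose and 0 fell) on the high-fat diet, with camera adjusted p = 0.000375, and adjusted p = 0.483 with an estimated correlation. Hbb-bs and Hba-a1 rose from 25.8 ± 12.2 to 856 ± 467 TPM (4.93, adjusted p = 3.9e-05) and from 15.9 ± 7.59 to 507 ± 272 TPM (4.85, adjusted p = 4.02e-05), in the same livers as the neutrophil and chemokine groups. In all, 6138 genes were called, 3213 higher and 2925 lower in IRI livers, and 2327 with a log2 fold change of at least 1 (1458 higher, 869 lower). The balance turned with quantile normalization (3160 higher, 3844 lower), with sample weights (4179 and 4356), without HFD-Sham 3 (2556 and 2683) and without HFD-IRI 2 (2456 and 2535). Without the first ND-Sham and ND-IRI libraries, which entered only the shared estimate of the spread, 7172 genes were called. Of the 37 lists, 17 were called by camera (11 up, 6 down), 0 with an estimated correlation (smallest adjusted p = 0.483) and 19 by fry.

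The responses to IRI on the 2 diets resembled each other. Across the 13364 genes the log2 fold changes correlated at Pearson r = 0.869 (Spearman rho = 0.867), with a slope of 0.853 for the high-fat over the normal diet. Genes are not independent replicates, so no p is given. Of the genes called higher, 2803 were shared, against 970 for independent lists of these sizes, and of those called lower, 1798 were shared, against 484. Of the genes called higher on the normal diet, 10 were called lower on the high-fat diet, and 4 were the other way round. Without the first ND-Sham and ND-IRI libraries r was 0.822.

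**Figure D2:**
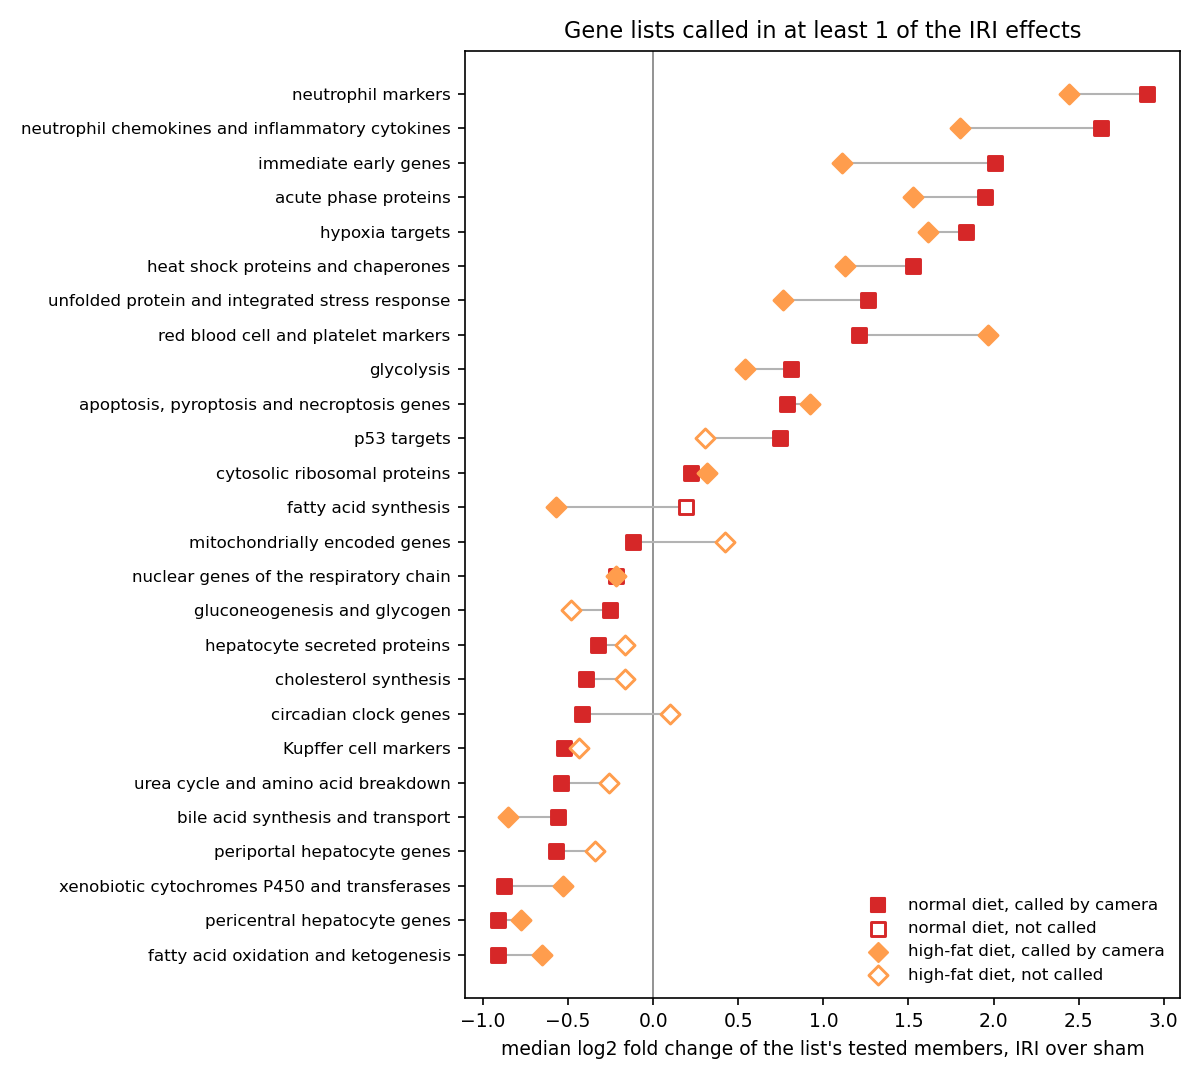
Median log2 fold change, IRI over sham, of the tested members of each gene list called by camera in at least 1 of the IRI effects, with the normal diet as squares and the high-fat diet as diamonds, and filled symbols for called lists. Neutrophil chemokines and inflammatory cytokines had medians of 2.63 and 1.81, and fatty acid oxidation and ketogenesis -0.91 and -0.65; none of these calls held with an estimated correlation.

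The comparison of the diets in sham livers asked what 4 months of high-fat feeding changed without ischemia. Of the tested members, 12 of 21 lipid droplet and fatty acid uptake genes rose, and 11 of 15 sex-biased, 8 of 21 urea cycle and amino acid and 7 of 16 periportal genes fell. The adjusted p with an estimated correlation was 0.116, 0.0286, 0.0589 and 0.0242 for these lists. Cyp2b9 and Cyp2a4, cytochromes P450 known as female-biased in mouse liver, rose from 0.447 ± 0.272 to 506 ± 48.2 TPM (log2 fold change 8.46, SE 0.216, adjusted p = 6.22e-10) and from 0.750 ± 0.577 to 71.8 ± 34.8 TPM (log2 fold change 5.30, SE 0.419, adjusted p = 3.81e-05), and the related Cyp2a22 rose from 6.10 ± 4.08 to 123 ± 5.98 TPM (4.28, adjusted p = 8.41e-05). Serpina1e, an alpha-1 antitrypsin gene, fell from 9090.3 ± 1883 to 154 ± 56.2 TPM (log2 fold change -5.93, SE 0.282, adjusted p = 3.33e-07). Hsd3b5, a male-biased hydroxysteroid dehydrogenase, fell from 60.7 ± 35.8 to 0.270 ± 0.140 TPM (log2 fold change -5.36, SE 0.437, adjusted p = 4.73e-05). Cyp4a12b, a male-biased fatty acid hydroxylase, fell from 85.5 ± 25.01 to 4.41 ± 2.13 TPM (-4.05, adjusted p = 0.00118).

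Apoa4, an apolipoprotein of triglyceride-rich particles, rose with the diet from 199.7 ± 54.2 to 3093 ± 2439 TPM (3.71, adjusted p = 0.00178). Sprr1a rose from 0.0433 ± 0.0751 to 26.4 ± 31.6 TPM (4.00, adjusted p = 0.00679). Ly6d, a lymphocyte antigen family member, rose from 7.28 ± 5.98 to 136 ± 112 TPM (3.95, adjusted p = 0.0231). The major urinary protein transcripts Mup7, Mup8 and Mup14 fell by 4.27, 4.01 and 3.82 on the log2 scale (adjusted p = 0.0103, 0.016 and 0.0407), and the summed TPM of all 22 Mup genes went from 40060 ± 5878 to 17415 ± 7449. Cidec rose from 31.3 ± 7.43 to 184 ± 143 TPM (2.23, adjusted p = 0.0312). Hmox1 was at 41.8 ± 23.1 and 86.2 ± 47.9 TPM (adjusted p = 0.167). Alb was at 77587 ± 9732 and 71818 ± 8619 TPM (adjusted p = 0.743). Without HFD-Sham 2 the calls of Ly6d, Mup8, Mup14 and Cidec were lost (adjusted p = 0.112, 0.077, 0.182 and 0.126). At least 1 of these calls was also lost on leaving out each other sham library. Without ND-Sham 1 these were those of Mup14 and Cidec (0.0585 and 0.0501), without ND-Sham 2 those of all 4 (0.0736 to 0.121), and without ND-Sham 3 those of all 4 (0.0673 to 0.135). Without HFD-Sham 1 they were those of Ly6d and Mup14 (0.0572 and 0.124), and without HFD-Sham 3 that of Cidec (0.0615). The call of Mup14 was lost under all 3 scaling alternatives (0.0511 to 0.0598), and that of Cidec under median-ratio scaling (0.0588) and quantile normalization (0.0657).

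Of the major urinary and sex-biased genes, 1 of 15 tested members rose, 11 fell and 3 did not pass (adjusted over the list alone, 1 rose and 13 fell), with camera adjusted p = 5.77e-21, and adjusted p = 0.0286 with an estimated correlation. The list mixes male-biased genes with female-biased ones, among them Cyp2a4, the member that rose. For lipid droplet and fatty acid uptake, 12 of 21 tested members rose and 9 did not pass (adjusted over the list alone, 15 rose and 0 fell), with camera adjusted p = 8.38e-10, and adjusted p = 0.116 with an estimated correlation. Cd36, a fatty acid transporter, rose from 35.2 ± 4.04 to 311 ± 33.6 TPM (log2 fold change 3.11, SE 0.134, adjusted p = 1.53e-07). Mogat1, a triglyceride synthesis enzyme, rose from 1.26 ± 0.358 to 18.1 ± 7.99 TPM (3.02, adjusted p = 8.04e-05). For fatty acid oxidation and ketogenesis, 9 of 26 tested members rose and 17 did not pass (adjusted over the list alone, 16 rose and 0 fell), with camera adjusted p = 3.91e-07, and adjusted p = 0.272 with an estimated correlation. Vnn1, a pantetheinase, rose from 72.8 ± 20.6 to 344 ± 42.6 TPM (2.26, adjusted p = 3.81e-05). Bdh1 rose from 148 ± 24.5 to 280.0 ± 23.8 TPM (0.93, adjusted p = 0.00212). Of the NRF2 antioxidant targets, 6 of 24 tested members rose and 18 did not pass (adjusted over the list alone, 15 rose and 0 fell), with camera adjusted p = 1.93e-05, and adjusted p = 0.3 with an estimated correlation. Gsta1, a glutathione transferase, rose from 3.77 ± 2.16 to 53.2 ± 36.4 TPM (adjusted p = 0.0109, and 0.0583 without HFD-Sham 2). Abcc3, a conjugate exporter, rose from 208 ± 19.8 to 306 ± 9.57 TPM (adjusted p = 0.0115, 0.0538 without ND-Sham 2, 0.0592 without HFD-Sham 2 and 0.21 with median-ratio scaling). Of the hepatic stellate cell and fibrosis markers, 8 of 17 tested members rose and 9 did not pass (adjusted over the list alone, 11 rose and 0 fell), with camera adjusted p = 3.17e-05, and adjusted p = 0.37 with an estimated correlation.

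For the urea cycle and amino acid breakdown, 8 of 21 tested members fell and 13 did not pass (adjusted over the list alone, 1 rose and 10 fell), with camera adjusted p = 1.95e-17, and adjusted p = 0.0589 with an estimated correlation. Asl, argininosuccinate lyase of the urea cycle, fell from 831 ± 159 to 240.4 ± 70.4 TPM (log2 fold change -1.80, SE 0.244, adjusted p = 0.00174). Hal, histidine ammonia-lyase, fell from 270.3 ± 31.0 to 107 ± 18.2 TPM (log2 fold change -1.33, SE 0.211, adjusted p = 0.00441). Of the periportal hepatocyte genes, 1 of 16 tested members rose, 7 fell and 8 did not pass (adjusted over the list alone, 2 rose and 7 fell), with camera adjusted p = 8.38e-10, and adjusted p = 0.0242 with an estimated correlation. Etnppl, an ethanolamine-phosphate lyase, fell from 92.0 ± 24.9 to 21.0 ± 7.41 TPM (-2.09, adjusted p = 0.00588). Of the cytosolic ribosomal proteins, 0 of 22 tested members rose, 0 fell and 22 did not pass (adjusted over the list alone, 0 rose and 0 fell), with camera adjusted p = 5.88e-10, and adjusted p = 0.343 with an estimated correlation; Rps18 and Rpl3 had log2 fold changes of -0.30 and -0.30 (adjusted p = 0.112 and 0.177). For cholesterol synthesis, 0 of 22 tested members rose, 0 fell and 22 did not pass (adjusted over the list alone, 0 rose and 0 fell), with camera adjusted p = 1.05e-06, and adjusted p = 0.497 with an estimated correlation, and camera adjusted p = 0.536 without ND-Sham 2. Hsd17b7 and Cyp51, enzymes of that pathway, had log2 fold changes of -0.62 and -0.71 (adjusted p = 0.216 and 0.304). For the xenobiotic cytochromes P450 and transferases the median log2 fold change was -0.32 and the mean 0.10, with camera pointing down (adjusted p = 0.00102, and adjusted p = 0.408 with an estimated correlation) and fry up (0.266). The camera call was lost with quantile normalization (0.137).

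**Figure D3:**
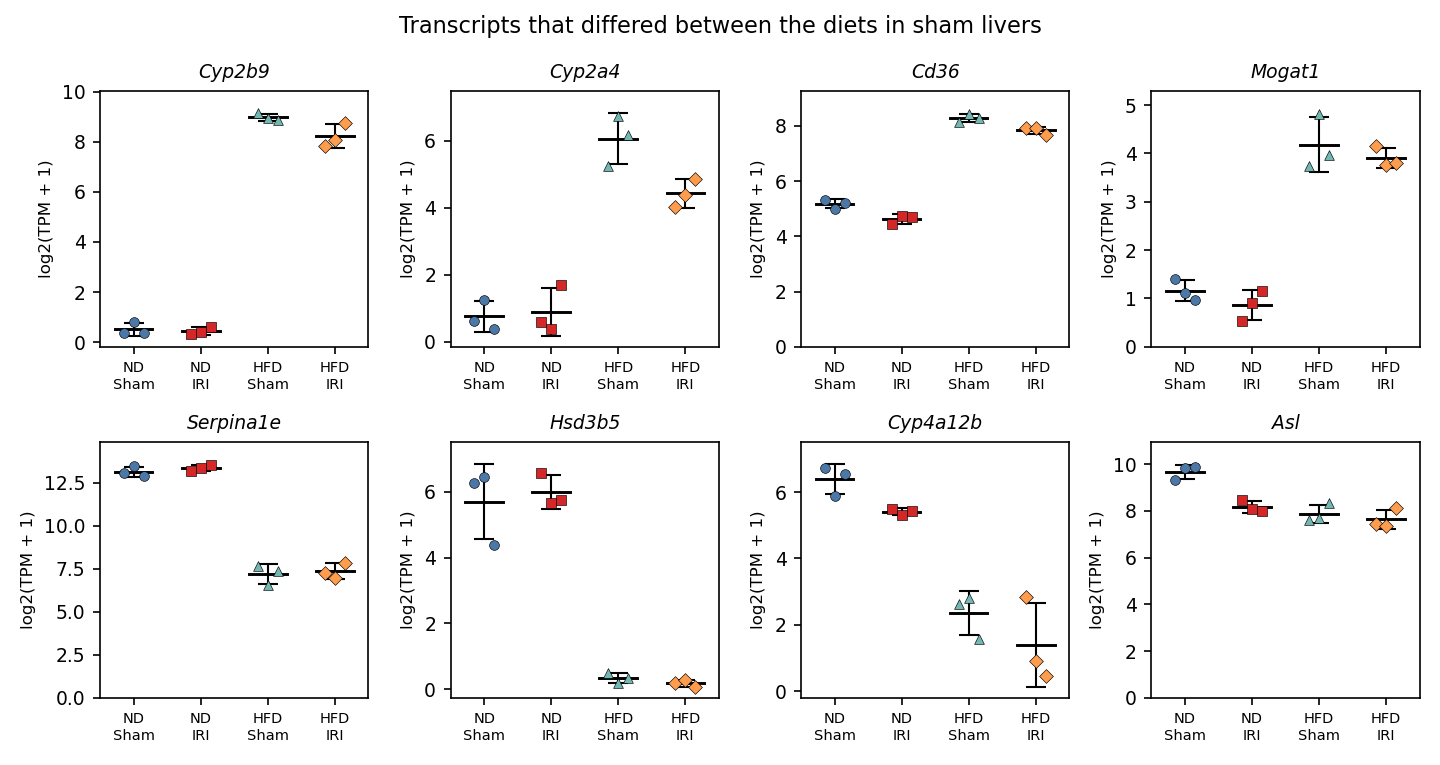
Expression of 8 transcripts in the 4 groups as log2(TPM + 1), with each point a library and lines and bars the mean ± SD of 3 libraries. Cyp2b9 was at 0.447 ± 0.272 TPM in ND-Sham and 506 ± 48.2 TPM in HFD-Sham livers, and Serpina1e at 9090.3 ± 1883 and 154 ± 56.2 TPM.

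In all, 780 genes were called between the diets in sham livers, 619 higher and 161 lower on the high-fat diet, and 315 with a log2 fold change of at least 1 (222 higher, 93 lower). The median over all genes was 0.17, which median-ratio scaling shifted by -0.16 and quantile normalization by -0.18. Then 493 genes (278 higher, 215 lower) and 579 genes (329 higher, 250 lower) were called. The count was 1730 without the first ND-Sham and ND-IRI libraries (1522 higher, 208 lower), 325 without ND-Sham 2, 311 without ND-Sham 3, 430 without HFD-Sham 1 and 248 without HFD-Sham 2. Of the 37 lists, 17 were called by camera (5 up, 12 down) and 9 by fry, and 2 held with an estimated correlation. The balance turned with quantile normalization (8 up, 5 down), with no filter (11 and 9), without ND-Sham 2 (8 and 7) and by fry (6 and 3).

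The comparison of the diets in IRI livers asked how injured steatotic livers differed from injured normal livers. Of the tested members, 16 of 26 fatty acid oxidation genes were higher on the high-fat diet, and 10 of 15 sex-biased and 4 of 16 periportal genes were lower. These list calls were lost with an estimated correlation (adjusted p = 0.0502 for each). Cyp4a14 was at 167 ± 61.9 TPM in ND-IRI and 1895 ± 330.4 TPM in HFD-IRI livers (log2 fold change 3.55, SE 0.353, adjusted p = 0.000171). Cyp4a10 was at 132 ± 32.9 and 1311 ± 109 TPM (log2 fold change 3.34, SE 0.208, adjusted p = 4.48e-06). Cyp2b9, Cyp2a22 and Cyp2a4 were higher by 7.77, 4.11 and 3.54 on the log2 scale. Slc22a27, an organic anion transporter family member, was at 0.797 ± 0.322 and 17.5 ± 4.75 TPM (3.35, adjusted p = 5.78e-06). Serpina1e was lower, at 10487 ± 1284 and 169 ± 54.7 TPM (log2 fold change -5.99, SE 0.282, adjusted p = 2.96e-07), as was Hsd3b5, at 65.5 ± 25.4 and 0.137 ± 0.0802 TPM (-5.81, adjusted p = 1.83e-05).

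Cyp4a12b had a log2 fold change of -4.02, adjusted p = 0.00116 between the diets in IRI livers, Mup8 of -5.60, adjusted p = 0.0029, Mup14 of -5.14, adjusted p = 0.0121, and Mup7 of -3.83, adjusted p = 0.0204. Ly6d was at 50.5 ± 37.7 and 467 ± 259 TPM (3.51, adjusted p = 0.0463). Hmox1 was at 1036 ± 129 and 1209 ± 275 TPM (adjusted p = 0.905). Cidec was at 54.9 ± 16.6 and 163 ± 81.2 TPM (0.204). Alb was at 74653 ± 11704 and 68019.5 ± 4601 TPM (0.832). The calls of Ly6d, Mup7 and Mup14 were lost without HFD-IRI 2 (adjusted p = 0.153, 0.0803 and 0.0559). That of Ly6d was also lost without HFD-IRI 1 (0.163) or any ND-IRI library (0.0579 to 0.0927), that of Mup7 without ND-IRI 2 or ND-IRI 3 (0.0586 and 0.0776), and that of Mup14 without ND-IRI 3 (0.0526).

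For fatty acid oxidation and ketogenesis in IRI livers, 16 of 26 tested members rose and 10 did not pass (adjusted over the list alone, 20 rose and 0 fell), with camera adjusted p = 2.56e-21, and adjusted p = 0.0502 with an estimated correlation. Vnn1 was at 27.1 ± 0.566 and 197 ± 14.8 TPM (2.81, adjusted p = 4.48e-06). For lipid droplet and fatty acid uptake, 6 of 21 tested members rose and 15 did not pass (adjusted over the list alone, 9 rose and 0 fell), with camera adjusted p = 1.87e-10, and adjusted p = 0.0933 with an estimated correlation. Cd36 was at 23.9 ± 2.82 and 229 ± 21.0 TPM (3.21, adjusted p = 1.05e-07). Fabp2, a fatty acid binding protein, was at 103 ± 3.70 and 329.8 ± 29.5 TPM (1.67, adjusted p = 4.47e-05). Of the hepatic stellate cell and fibrosis markers, 2 of 17 tested members rose and 15 did not pass (adjusted over the list alone, 5 rose and 0 fell), with camera adjusted p = 5.82e-05, and adjusted p = 0.435 with an estimated correlation. The collagen genes Col1a1 and Col1a2 were at 2.82 ± 0.439 and 14.2 ± 4.87 TPM (1.95, adjusted p = 0.0335), and at 2.21 ± 0.539 and 8.95 ± 2.57 TPM (1.61, adjusted p = 0.0334). Without HFD-IRI 2 their adjusted p was 0.124 and 0.123, and both calls were also lost without HFD-IRI 1 (0.105 and 0.0992) or ND-IRI 2 or ND-IRI 3 (0.0772 to 0.12), and that of Col1a1 without ND-IRI 1 (0.0737).

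Of the major urinary and sex-biased genes, 1 of 15 tested members rose, 10 fell and 4 did not pass (adjusted over the list alone, 1 rose and 13 fell) in IRI livers, with camera adjusted p = 2.41e-15, and adjusted p = 0.0502 with an estimated correlation. Of the acute phase proteins, 2 of 26 tested members fell and 24 did not pass (adjusted over the list alone, 0 rose and 2 fell), with camera adjusted p = 1.89e-06, and adjusted p = 0.41 with an estimated correlation. The members that fell were Itih3, a hyaluronan-binding inhibitor subunit, at 1069 ± 301 and 539.9 ± 39.7 TPM (-0.95, adjusted p = 0.02), and complement C3, at 3982 ± 645 and 2572 ± 409 TPM (-0.63, adjusted p = 0.0419). Of the neutrophil chemokines and inflammatory cytokines, 2 of 24 tested members fell and 22 did not pass (adjusted over the list alone, 1 rose and 4 fell), with camera adjusted p = 1.69e-05, and adjusted p = 0.435 with an estimated correlation. Lif was at 5.69 ± 0.767 and 2.53 ± 0.192 TPM (-0.92, adjusted p = 0.0143). Icam1, a leukocyte adhesion molecule, was at 46.4 ± 7.82 and 25.03 ± 5.92 TPM (-0.88, adjusted p = 0.0419). Selp was at 11.3 ± 2.58 and 22.96 ± 8.99 TPM (0.92, adjusted p = 0.0648). Leaving out 1 library ended calls. Without ND-IRI 2 these were those of Itih3, C3, Lif and Icam1 (0.075, 0.174, 0.0521 and 0.101), without ND-IRI 3 the same 4 (0.0579, 0.0762, 0.0644 and 0.075), and without ND-IRI 1 that of Icam1 (0.101). Without HFD-IRI 1 they were those of Itih3, C3 and Icam1 (0.0542, 0.171 and 0.144), without HFD-IRI 2 those of Itih3 and Icam1 (0.0625 and 0.144), and without HFD-IRI 3 those of Itih3 and C3 (0.0627 and 0.0807).

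Of the periportal hepatocyte genes in IRI livers, 4 of 16 tested members fell and 12 did not pass (adjusted over the list alone, 1 rose and 6 fell), with camera adjusted p = 1.09e-05, and adjusted p = 0.0502 with an estimated correlation. Cyp2f2, a periportal cytochrome P450, was at 1061 ± 127 and 603 ± 56.9 TPM (log2 fold change -0.81, SE 0.115, adjusted p = 0.00235). Hal was at 121 ± 16.0 and 40.0 ± 13.5 TPM (-1.61, adjusted p = 0.00146). For the urea cycle and amino acid breakdown, 3 of 21 tested members fell and 18 did not pass (adjusted over the list alone, 0 rose and 7 fell), with camera adjusted p = 1.69e-05, and adjusted p = 0.396 with an estimated correlation. Gls2, liver glutaminase, was at 199 ± 38.8 and 100.1 ± 25.9 TPM (-0.996, adjusted p = 0.0169), a call lost without HFD-IRI 1 or HFD-IRI 2 (0.0768 and 0.0646) and with median-ratio scaling (0.0582). Of the pericentral hepatocyte genes, 6 of 17 tested members rose and 11 did not pass (adjusted over the list alone, 9 rose and 1 fell), with camera adjusted p = 0.000136, and adjusted p = 0.396 with an estimated correlation.

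In all, 516 genes were called between the diets in IRI livers, 318 higher and 198 lower on the high-fat diet, and 246 with a log2 fold change of at least 1 (135 higher, 111 lower). The balance turned with sample weights (1738 higher, 2129 lower) and was nearer even with median-ratio scaling (235 and 195), quantile normalization (308 and 275) and TPM re-closed (280 and 248). The count was 739 without the first ND-Sham and ND-IRI libraries (382 higher, 357 lower), 240 without ND-IRI 2, 304 without ND-IRI 3, 253 without HFD-IRI 1 and 294 without HFD-IRI 2. Of the genes called in sham livers, 150 were also called higher and 59 also lower in IRI livers, against 14.7 and 2.39 for independent lists, and 2 were called in opposite directions. Of the 37 lists, 17 were called by camera (7 up, 10 down), 7 by fry and 0 with an estimated correlation, where the smallest adjusted p was 0.0502. The balance turned with sample weights (10 up, 8 down), without the first ND-Sham and ND-IRI libraries (11 and 7), without ND-IRI 1 (12 and 8), without HFD-IRI 2 (8 and 6) and by fry (5 and 2).

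The difference between the IRI effects asked whether the response to ischemia-reperfusion depended on the diet. The effects of IRI on Cyp4a10 and Cyp4a14 differed between the diets, with a large fall on the normal diet and values closer to sham on the high-fat diet. Higher and lower refer here to the effect of IRI on the high-fat diet less that on the normal diet. Cyp4a10 went from 2218 ± 382 to 132 ± 32.9 TPM on the normal diet and from 1746 ± 358 to 1311 ± 109 TPM on the high-fat diet (log2 difference 3.69, SE 0.294, adjusted p = 0.000379). Cyp4a14 went from 3684 ± 1544 to 167 ± 61.9 TPM and from 3532 ± 1608 to 1895 ± 330.4 TPM (log2 difference 3.63, SE 0.499, adjusted p = 0.0219). Cyp2e1 went from 11633 ± 688 to 2471 ± 282 TPM and from 14174 ± 2422 to 8823 ± 1001 TPM (1.56, adjusted p = 0.0219). Hsd17b10, a mitochondrial dehydrogenase, went from 447 ± 30.9 to 183 ± 5.10 TPM and from 427 ± 48.1 to 404 ± 67.6 TPM (1.19, adjusted p = 0.0404). Serpina7, thyroxine-binding globulin, went the other way, from 27.0 ± 9.89 to 194 ± 54.2 TPM on the normal diet and from 182 ± 48.1 to 158 ± 25.9 TPM on the high-fat diet (-3.01, adjusted p = 0.0166).

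The other called genes within the naming rule were Cyp2c38, from 42.9 ± 6.04 to 13.0 ± 1.52 TPM on the normal and from 113 ± 11.9 to 92.4 ± 8.25 TPM on the high-fat diet (log2 difference 1.35, adjusted p = 0.0245), and Cux2, a female-biased transcriptional repressor, from 5.83 ± 2.73 to 0.0867 ± 0.0321 TPM and from 0.237 ± 0.0862 to 0.0767 ± 0.0451 TPM (2.38, adjusted p = 0.0166). Nat8f5, an N-acetyltransferase family member, went from 8.55 ± 3.60 to 35.0 ± 9.24 TPM and from 17.4 ± 6.82 to 5.43 ± 2.62 TPM (-3.501, adjusted p = 0.0394). Osbpl3, an oxysterol-binding protein relative, went from 1.21 ± 0.0208 to 1.08 ± 0.0709 TPM and from 25.7 ± 15.5 to 2.71 ± 0.458 TPM (-2.62, adjusted p = 0.0404). Cux2 in HFD-Sham and Osbpl3 in ND-Sham livers were already near the pseudocount of 1 or below it, so a further fall with IRI could hardly register there. Col27a1, a fibrillar collagen, went from 6.46 ± 1.25 to 11.6 ± 2.53 TPM and from 11.6 ± 2.70 to 3.57 ± 0.297 TPM (-2.19, adjusted p = 0.0166). Cyb5b, an outer mitochondrial membrane cytochrome b5, went from 161 ± 11.3 to 157 ± 2.00 TPM and from 291 ± 16.7 to 137 ± 20.3 TPM (-1.06, adjusted p = 0.0394). The differences for Hmox1, Cidec and Alb were -0.87, -0.81 and -0.01 (adjusted p = 0.685, 0.785 and 0.99), and the Alb estimate ranged from -0.12 to 0.10 on leaving out single libraries.

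**Figure D4:**
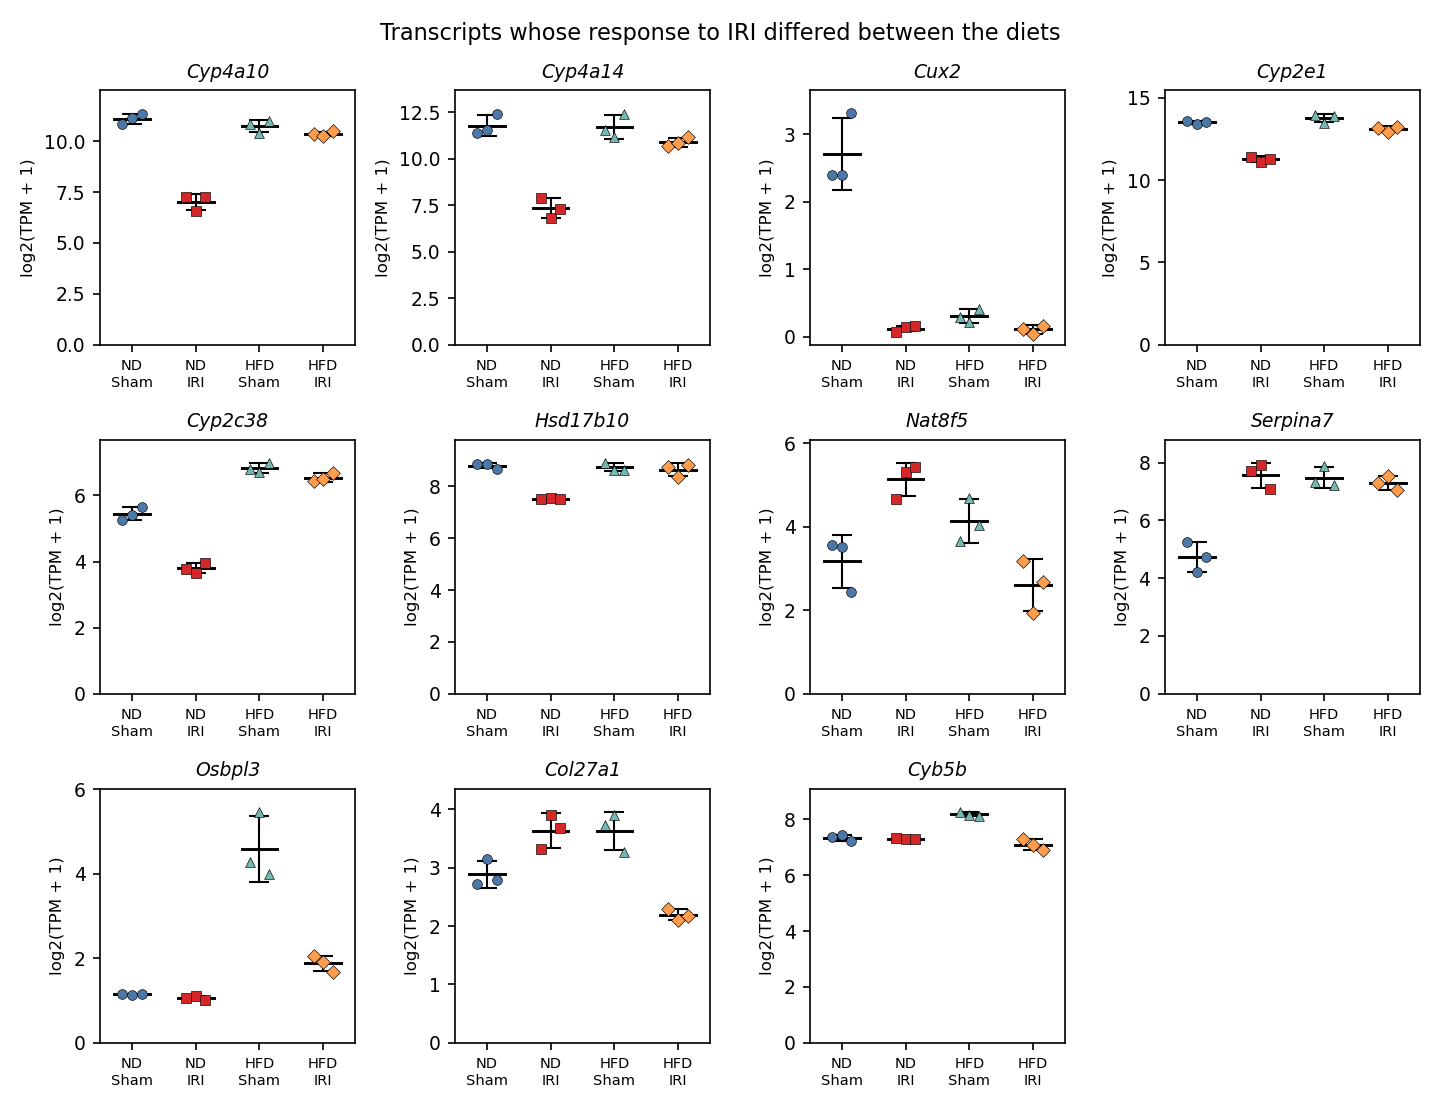
Expression of the 11 genes of the naming rule whose response to IRI differed between the diets, as log2(TPM + 1) in the 4 groups, with each point a library and lines and bars the mean ± SD of 3 libraries. Cyp4a10 was at 132 ± 32.9 TPM in ND-IRI and 1311 ± 109 TPM in HFD-IRI livers.

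Cyp4a10 kept its call on leaving out each of the 12 libraries, and each of the other 10 genes lost its call without at least 3 of them. Every 1 of the 10 lost it without HFD-IRI 3 (adjusted p = 0.0679 to 0.0708), and every 1 without ND-IRI 2 (0.0623 to 0.124). Without ND-Sham 3, all but Cux2 lost it (0.0702 to 0.131), and without ND-IRI 3, all but Serpina7 (0.0543 to 0.0846). Of these calls, leaving out ND-Sham 2 ended 6 (0.0539 to 0.109), HFD-IRI 1 ended 4 (0.0595 to 0.115), HFD-IRI 2 ended 5 (0.0612 to 0.0725) and HFD-Sham 2 ended 4 (0.0948 to 0.122). ND-Sham 1 ended 3 (0.0569 to 0.059), HFD-Sham 1 ended 3 (0.0538 to 0.113) and HFD-Sham 3 ended that of Hsd17b10 (0.0556). Median-ratio scaling, which shifted the median of all genes by 0.14, ended the calls of Cyp4a14 (0.0525), Cyp2e1, Cyp2c38, Hsd17b10, Nat8f5, Osbpl3 and Cyb5b (up to 0.15). The replicate block ended those of Hsd17b10, Nat8f5, Osbpl3 and Cyb5b (0.0545 to 0.0663), no filter those of Cyp2e1, Hsd17b10, Nat8f5 and Osbpl3 (0.0598 to 0.0992), and no variance trend those of Hsd17b10 and Cyb5b (0.0636 for each).

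Relative to other genes, 15 lists were called between the IRI effects by camera, and 0 with an estimated correlation (smallest adjusted p = 0.511) or by fry. For fatty acid oxidation and ketogenesis, 2 of 26 tested members were higher and 24 did not pass (adjusted over the list alone, 4 were higher and 0 were lower), with camera adjusted p = 9.67e-07, and adjusted p = 0.511 with an estimated correlation. Of the mitochondrially encoded genes, 0 of 13 tested members were higher, 0 were lower and 13 did not pass (adjusted over the list alone, 0 were higher and 0 were lower), with camera adjusted p = 9.67e-07, and adjusted p = 0.511 with an estimated correlation. mt-Cytb and mt-Nd2, subunits of respiratory complexes, had differences of 0.74 and 0.66 (adjusted p = 0.248 and 0.254). Of the neutrophil chemokines and inflammatory cytokines, 0 of 24 tested members were higher, 0 were lower and 24 did not pass (adjusted over the list alone, 1 was higher and 10 were lower), with camera adjusted p = 4.59e-06, and adjusted p = 0.511 with an estimated correlation. Il1rn and Ccl2 had differences of -1.67 and -3.44 (adjusted p = 0.0855 and 0.089, and 0.0122 for Ccl2 without HFD-Sham 3). Il1rn was at 1.77 to 2.63 TPM in ND-Sham and 6.37 to 10.3 in HFD-Sham libraries. After IRI it was at 40.95 to 66.8 TPM on the normal and 39.3 to 69.1 on the high-fat diet. Its difference therefore lay mainly in the higher HFD-Sham values. Ccl2 was at 0.58 to 1.51 and 3.12 to 16.9 TPM in those sham groups. After IRI it was at 74.9 to 92.1 and 24.2 to 72.8 TPM, without overlap in either case. Of the xenobiotic cytochromes P450 and transferases, 2 of 22 tested members were higher and 20 did not pass (adjusted over the list alone, 5 were higher and 0 were lower), with camera adjusted p = 1.53e-05, and adjusted p = 0.511 with an estimated correlation. Of the pericentral hepatocyte genes, 1 of 17 tested members was higher and 16 did not pass (adjusted over the list alone, 2 were higher and 0 were lower), with camera adjusted p = 0.000144, and adjusted p = 0.511 with an estimated correlation, and Oat had a difference of 1.34 (adjusted p = 0.0967).

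For the urea cycle and amino acid breakdown, 0 of 21 tested members were higher, 0 were lower and 21 did not pass (adjusted over the list alone, 0 were higher and 0 were lower) between the IRI effects, with camera adjusted p = 0.000144, and adjusted p = 0.511 with an estimated correlation, and Asl and Hpd, enzymes of arginine synthesis and tyrosine breakdown, had differences of 1.27 and 0.91 (adjusted p = 0.18 and 0.291). Of the cytosolic ribosomal proteins, 0 of 22 tested members were higher, 0 were lower and 22 did not pass (adjusted over the list alone, 0 were higher and 0 were lower), with camera adjusted p = 0.00163, and adjusted p = 0.683 with an estimated correlation, and Rps18 and Rps9 had differences of 0.28 and 0.19 (adjusted p = 0.547 and 0.721). Both camera calls were lost with quantile normalization (0.108 and 0.078). Of the NRF2 antioxidant targets, 0 of 24 tested members were higher, 0 were lower and 24 did not pass (adjusted over the list alone, 0 were higher and 0 were lower), with camera adjusted p = 0.00307, and adjusted p = 0.511 with an estimated correlation, and camera adjusted p = 0.183 without ND-Sham 1 and 0.107 without the first ND-Sham and ND-IRI libraries. Gsta4 and Gsta1, glutathione transferases, had differences of -0.83 and -3.11 (adjusted p = 0.155 and 0.222, the latter 0.0459 without ND-IRI 1). Gsta1 was at 1.39 to 5.61 TPM in ND-Sham and 32.0 to 95.3 in HFD-Sham libraries. After IRI it was at 14.6 to 98.7 and 41.6 to 93.9 TPM, so the diets overlapped there. Gsta4 overlapped in sham livers (100.5 to 118.4 and 96.95 to 143.3 TPM) but not after IRI (126.5 to 132.0 and 67.4 to 90.2 TPM).

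In all, 13 genes were called between the IRI effects, 6 with a higher and 7 with a lower effect on the high-fat diet, against 1345 at an unadjusted p under 0.05. The median difference over all genes was -0.13, so a list could stand above other genes with a median near 0. The count was 335 without the first ND-Sham and ND-IRI libraries (66 higher, 269 lower) and 89 without ND-IRI 1 alone. It was 8 without ND-Sham 2, HFD-Sham 2, HFD-IRI 1 or HFD-IRI 2, and 3 without ND-Sham 3 or ND-IRI 3. It was 2 without ND-IRI 2 or HFD-IRI 3, and 27 without HFD-Sham 3. Of the 37 lists, 15 were called by camera (10 up, 5 down), 0 by fry and 0 with an estimated correlation, where the smallest adjusted p was 0.511. The balance turned with quantile normalization (4 up, 5 down), without ND-Sham 2 (7 and 9) and without HFD-IRI 3 (6 and 7).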

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

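The tests of the Cyp4a, sex-biased and clock patterns below were chosen after the results were seen; the splits of the samples were planned. The test of the difference between the IRI effects singled out 13 genes, and camera 15 lists. With an estimated correlation 0 of these lists was called (smallest adjusted p = 0.511), and 0 by fry.

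The log2 differences between the IRI effects (high-fat less normal diet) were positive for Cyp4a10 (3.69), Cyp4a14 (3.63), Cux2 (2.38), Cyp2e1 (1.56), Cyp2c38 (1.35) and Hsd17b10 (1.19). They were negative for Cyb5b (-1.06), Tmem171 (-1.98), Lce1d (-2.16), Col27a1 (-2.19), Osbpl3 (-2.62), Serpina7 (-3.01) and Nat8f5 (-3.50). Tmem171 and Lce1d (adjusted p = 0.0394 and 0.0024) lie outside the naming rule and were not run under the alternatives. Lce1d was listed at 0 in the ND-Sham libraries, so its value depends on the pseudocount. Those of Cux2, at 0.237 TPM in HFD-Sham, and Osbpl3, at 1.21 TPM in ND-Sham livers, do so as well. The same holds for Tmem171, at 0.193 TPM in ND-Sham livers and at most 2.97 TPM in any group.

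The lists that differed by camera had median log2 differences of 0.27 (fatty acid oxidation and ketogenesis), 0.63 (mitochondrially encoded genes), -0.91 (neutrophil chemokines and inflammatory cytokines), 0.22 (xenobiotic cytochromes P450 and transferases), 0.14 (pericentral hepatocyte genes), 0.19 (urea cycle and amino acid breakdown), 0.074 (cytosolic ribosomal proteins) and -0.56 (NRF2 antioxidant targets). The others were the unfolded protein and integrated stress response (-0.57), fatty acid synthesis (-0.73), red blood cell and platelet markers (0.61), hepatocyte secreted proteins (0.15), heat shock proteins and chaperones (-0.36), T, B and NK cell markers (0.29) and circadian clock genes (0.028). The median of all genes was -0.13. Leaving out 1 library ended the camera call of several lists: T, B and NK cell markers (ND-Sham 1, ND-IRI 2, ND-IRI 3, HFD-Sham 2, HFD-Sham 3 or HFD-IRI 3, adjusted p up to 0.198), red blood cell and platelet markers (ND-Sham 2 or HFD-IRI 3, up to 0.0738), hepatocyte secreted proteins (ND-Sham 2, ND-IRI 3 or HFD-IRI 3, up to 0.181) and the unfolded protein response (ND-Sham 1, 0.0996). The same held for heat shock proteins (ND-Sham 1, ND-IRI 1, HFD-Sham 2, HFD-Sham 3, HFD-IRI 1 or HFD-IRI 2, up to 0.997), NRF2 targets (ND-Sham 1, 0.183), fatty acid synthesis (ND-Sham 1, ND-IRI 1, HFD-Sham 2 or HFD-IRI 2, up to 0.648) and clock genes (ND-Sham 2, ND-Sham 3, ND-IRI 2, ND-IRI 3, HFD-Sham 2 or HFD-IRI 3, up to 0.299).

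Cyp4a10 and Cyp4a14 fell with IRI on the normal diet, and on the high-fat diet their estimated change was far smaller. Scaling between samples is argued against by Cyp4a10, whose difference stayed at 3.48 (SE 0.262) where it was smallest, under quantile normalization. The scaling alternatives shifted the median difference of all genes by at most 0.14. A loss of a difference this large was therefore unlikely from the outset. Under median-ratio scaling the call of Cyp4a14 ended (3.80, SE 0.610, adjusted p = 0.0525, against 3.63, SE 0.499, adjusted p = 0.0219) because its SE rose. Reads shared within the family are argued against by the summed TPM of 8 Cyp4a genes, whose difference was 2.69 (SE 0.405). A weaker loss of other fatty acid oxidation transcripts in steatotic livers stays open: the 23 other members had a median difference of 0.20, with camera p = 0.000475 and 0.169 with an estimated correlation.

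Of the 15 major urinary and sex-biased genes tested, 11 were called lower with the high-fat diet in sham livers (list adjusted p = 0.0286 with an estimated correlation) and 10 in IRI livers (0.0502). Female mice among these samples are argued against by a summed TPM of 4 Y-linked genes of at least 93.0 in high-fat-diet libraries, against at least 83.2 in normal-diet libraries, with Xist at most 0.07. Reads shared within families are argued against as the whole of the fall by the family sums in sham livers, which differed by -1.28 (SE 0.361, 22 Mup genes) and -1.22 (SE 0.148, 6 Serpina1 genes), although both are far less than the values of single members (-4.27, -4.01 and -3.82 for Mup7, Mup8 and Mup14, and -5.93 for Serpina1e), so how far single members fell stays open. A shift of the whole sex-biased programme towards the female pattern stays open. Of 17 female-biased genes tested, 6 were called higher and 1 lower, Cux2 (-2.40), with the high-fat diet in sham livers. In IRI livers 10 were called higher and 0 lower. Of these, Acot3, Atp6v0d2, Cyp17a1 and Fmo2 were not called in sham livers. With IRI on the normal diet their means went from 36.6 to 2.95, 6.26 to 1.59, 13.3 to 6.98 and 27.3 to 4.03 TPM. Their calls therefore cannot tell a shift with diet from a different response to IRI. Cux2 (-0.01, adjusted p = 0.991) was at 0.0867 and 0.0767 TPM in the IRI groups, so a lower value could hardly register.

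Of 17 clock genes tested, 5 rose and 8 fell with IRI on the normal diet, and 5 rose and 6 fell on the high-fat diet. As a list they were called by camera on the normal diet only (adjusted p = 0.0488, lost under each scaling alternative, and adjusted p = 0.452 with an estimated correlation), and not on the high-fat diet (0.617, and 0.838 with an estimated correlation). The list mixes genes that peak at opposite times of day, so rises and falls can cancel in camera. These list results therefore cannot show whether the clock shift differed between the diets. Of the hepatocyte secreted proteins, 0 of 18 fell as far as the median of the clock genes that fell on the normal diet (-2.34). This list fell too, with 8 members called lower, 1 higher and a median of -0.33. Its camera adjusted p was 0.00387, and 0.347 with an estimated correlation. A lower share of hepatocyte RNA is therefore argued against only as the whole of the fall of those clock genes, and a smaller loss stays open. A different time of day at collection stays open, since the labels give no collection times: 21 of 24 calls over both IRI effects had the direction that the gene's phase gives, while among the others Per1 rose on the high-fat diet against it.

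Other splits of the 6 libraries of a contrast were too few (10) for a share under 0.05. The real split called 6248, 6138, 780 and 516 genes in the order of the report, it was the 1 split of 10 with as many calls in each, and the highest other split called 1, 1, 2 and 382. The split with 382 set ND-IRI 1, HFD-IRI 1 and HFD-IRI 3 against ND-IRI 2, ND-IRI 3 and HFD-IRI 2. For the difference between the IRI effects, 3 of 100 relabellings drawn from 200, the real one included, gave as many calls as the real labels (12 on residuals of the additive model). That share was under 0.05, but false relabellings called far more genes than the real labels, so the count could not exclude chance. The highest other called 602, several times the real count, and divided the IRI libraries in that same way. Another called 495 and divided them differently, with ND-IRI 1, HFD-IRI 1 and HFD-IRI 2 against the rest. Such counts point to a structure of the samples beyond diet and operation.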

How the results depend on the processing

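The values without the first ND-Sham and ND-IRI libraries were chosen after the data were seen; all other alternatives were planned. Of 2569 values of single genes under alternatives, 2325 kept their direction and side of the threshold, 203 lost their call, 22 gained one, 5 moved and 14 reversed. Of 1800 values of single lists, 1503 kept both, 291 lost their call and 6 reversed. Causes were not tested unless stated.

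Counts of called genes moved as follows. At a log2 fold change of at least 1 they were 2523 and 2327 for IRI on the normal and high-fat diet, and 315 and 246 for diet in sham and IRI livers, by construction lower. Sample weights gave 5102 and 3867 for diet in sham and IRI livers and 4380 for the difference between the IRI effects, with weights from 0.216 (ND-IRI 1) to 5.71 (ND-Sham 3). With only the groups compared, fewer samples gave 367 and 304 for diet. Median-ratio scaling gave 493 for diet in sham livers. Without the first ND-Sham and ND-IRI libraries, 1730 were called for diet in sham livers and 335 for the difference. The difference also moved to 25 with pseudocount 0.1, 21 with no filter and 21 with quantile normalization.

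Leaving out 1 library gave 4903 to 6633 genes for IRI on the normal diet, 4930 to 5606 on the high-fat diet, 248 (HFD-Sham 2) to 1047 (ND-Sham 1) for diet in sham livers, 240 (ND-IRI 2) to 609 (ND-IRI 1) for diet in IRI livers and 2 (ND-IRI 2, HFD-IRI 3) to 89 (ND-IRI 1) for the difference. A group left with 2 libraries had its spread pooled with the others. Replicate numbers did not pair the libraries across all groups. Of 18 same-number pairs, 3 had r above 0.1, and 0 of 12 libraries correlated best with their own number in every other group. Pairing within an operation could not be excluded this way. Same-number pairs across the diets had r of 0.396, 0.0756 and 0.274 in sham livers, and of 0.0729, 0.418 and -0.177 in IRI livers. With the number as a replicate block, 5879, 5762, 568, 448 and 9 genes were called.

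With an estimated correlation 0 lists were called for IRI on the normal diet, 0 on the high-fat diet, 2 and 0 for diet in sham and IRI livers and 0 for the difference. By fry 9 and 7 were called for diet in sham and IRI livers and 0 for the difference. By camera with quantile normalization 9 were called for the difference, against 15.

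The reversed values were these. For Alb, IRI on the normal diet ranged from -0.18 to 0.047 on leaving out 1 library, and the difference between the IRI effects was 0.16 with median-ratio scaling, 0.14 with sample weights, 0.21 without the first ND-Sham and ND-IRI libraries and -0.12 to 0.10 on leaving out 1 library. For Cidec, IRI on the high-fat diet was 0.48 with sample weights and -0.60 to 0.57 on leaving out 1 library, and for Hmox1 the difference was 0.10 with sample weights. Lists that changed direction were xenobiotic cytochromes P450 and transferases for diet in sham livers by fry (adjusted p = 0.266), fatty acid synthesis and cholesterol synthesis for diet in IRI livers with sample weights (0.366 and 0.763), and for the difference heat shock proteins and chaperones without the first ND-Sham and ND-IRI libraries (0.632) and fatty acid synthesis with sample weights (0.817) and without those libraries (0.680).

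The correlation of the IRI effects, 0.869, was 0.858 with pseudocount 0.1, 0.852 with no filter, 0.887 with the filter at 5 TPM, 0.857 re-closed, 0.822 without the first ND-Sham and ND-IRI libraries and 0.844 to 0.877 on leaving out 1 library. The cause was not tested. Sequencing depth is unknown, so its effect on genes near 0 TPM could not be measured.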

Other observations

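The lists of this part were planned, and the library values were looked up after the data were seen. Of the p53 targets, 10 of 18 tested members rose, 2 fell and 6 did not pass (adjusted over the list alone, 11 rose and 2 fell) on the normal diet, with camera adjusted p = 0.0469, and adjusted p = 0.284 with an estimated correlation. This call was lost without ND-Sham 1 (0.101), ND-IRI 1 (0.0734) or both (0.182). Of the apoptosis, pyroptosis and necroptosis genes, 14 of 23 tested members rose, 3 fell and 6 did not pass (adjusted over the list alone, 15 rose and 3 fell) on the normal diet and 13 of 23 tested members rose, 4 fell and 6 did not pass (adjusted over the list alone, 14 rose and 4 fell) on the high-fat diet, with camera adjusted p = 0.00741, and adjusted p = 0.409 with an estimated correlation on the former. Of the Kupffer cell markers, 5 of 13 tested members fell and 8 did not pass (adjusted over the list alone, 0 rose and 4 fell) on the normal diet, with camera adjusted p = 0.00701, and adjusted p = 0.523 with an estimated correlation, while for recruited monocyte and macrophage markers camera adjusted p was 0.0625. For proliferation genes and for ferroptosis and iron genes it was 0.315 and 0.249. Lists not called against other genes still held called members on the normal diet. Of the recruited monocyte and macrophage markers, 8 of 16 rose and 1 fell. Of the proliferation genes, 4 of 13 rose and 0 fell, and of the ferroptosis and iron genes, 8 of 17 rose and 4 fell. By fry the adjusted p of these 3 lists was 0.0245, 0.104 and 0.000371, and that of the Kupffer cell markers 0.112. Of the interferon-stimulated genes, 5 of 24 tested members rose and 19 did not pass (adjusted over the list alone, 13 rose and 0 fell) with the high-fat diet in sham livers, with camera adjusted p = 0.000276, and adjusted p = 0.6 with an estimated correlation.

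The third principal component divided libraries within groups. All 24 immediate early genes tested loaded below 0 on it, and 22 of 26 acute phase proteins above 0. The first ND-Sham library, at 30.5, held 5.09 TPM of Pdk4 (176.3 and 396.2 in the others), 82.4 of Igfbp1 (1604 and 2255) and 73.8 of Jchain (1.97 and 4.96). The first ND-IRI library, at -20.1, held 518 TPM of Pdk4 (133 and 159 in the others) and 408 of Saa1 (2037 and 1207).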
